A study of Mus musculus with 6 samples.

How the data were processed

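RNA from back skin of 6 C57BL/6 mice, 3 exposed to UVB and 3 not, was labelled with Cy3 and hybridised to Agilent mouse arrays with 1 colour, starting from 0.2 µg of RNA per the labels. Groups and replicate numbers were taken from the sample titles. Per the labels, each group held 3 mice, so that limma p-values of single genes measure the spread between mice. Those of camera at a preset correlation, of hypergeometric tests and of permutations of genes or probe pairs instead weigh genes against other genes.

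The authors deposited the scanner output of each array and a table of processed values. Per the file headers, the spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, with spatial and multiplicative detrending, outlier flagging and surrogate values for dim spots. The processed intensity per the file headers is not scaled between arrays. The deposited table holds log2 values: sorted, its 6 columns were alike within 0.00212, so that quantile normalization was inferred from the values, and each column correlated with the log2 signal of its own array at r of 0.99866 to 0.99995. Each deposited column had a median of 4.95 on the log2 scale. How the authors made that table is not given in the sources used here. Its scale and centring were known only from this comparison, and it was used as an alternative.

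From the processed intensity, log2 values were taken and each array's 75th percentile over spots that were not controls (302 to 519 in signal) was subtracted. That percentile was 363, 519 and 484 on control arrays 1 to 3 and 352, 315 and 302 on UVB arrays 1 to 3. Probes at background can then stand higher on UVB arrays. Kdm5d, not well above background on any array, lay at -7.41 to -7.03 in controls and -6.80 to -6.45 after UVB. Rises of dim genes can hold such an offset. Control spots and spots flagged as outliers (135 to 274 per array) were left out, spots of a probe were averaged, and a probe was tested where it was well above background on at least 3 of the 6 arrays. Of 55681 probes, 26582 were named through a RefSeq accession in a gene table of assembly GRCm38.p6 and 3094 through their symbol, and 26005 kept the name in the files. That table was used for names only, and probe positions are those of the files, in mm9. Each gene was represented by the tested probe with the highest mean over all 6 arrays, which left 24355 targets. Gene values can therefore rest on a probe that other probes of the gene do not follow: of 91 list genes with over 1 tested probe, 16 had probes of both signs, 1 of them, Trp63, called.

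UVB was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). No covariate was used. Errors beside log2 fold changes are limma standard errors. Where a probe was not well above background on any array of a group, the difference is given as a bound: the mean of the other group against the mean, over arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. Such bounds hold for the background treatment of the files and were not reached with normexp. The gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over 27 lists, beside camera with an estimated correlation and fry. List medians were the same to 2 decimals with such genes set to their bound. All 16 lists that passed at the preset correlation no longer passed with the estimated one. Of these 16, 8 did not pass the directional fry test. The rule named the 6 largest rises and 6 largest falls among passing named genes whose groups did not overlap, the 2 members of smallest p in each passing list, and Cdkn1a, Krt6a, Krt16, Il1b, Ptgs2, Mmp3, Mmp13, Tyr, Dct, Col1a1 and Mki67. Other genes were chosen after their values were seen, as examples of their list, and the values of some list members are not reported here.

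The steps were tested on 5 simulated data sets drawn from the means and residual spread of the 24355 targets in the UVB comparison, with 200 changed genes each. Of 2-fold changes 39.0% and of 4-fold changes 76.0% were recovered, with 5.40 unchanged genes called per data set. A list shifted by 2-fold passed in all 5 data sets, and some other list passed in 2 of them. Simulated genes were drawn independently, while the shifted list, cell cycle, had an estimated correlation of 0.80 in the data. The simulation thus cannot show how camera behaves on correlated lists. It planted 200 changes where 3058 targets were called in the data, so its recovery rates need not carry over.

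All 6 arrays lay on 1 slide with 1 scan time, so no slide block was possible. The alternatives were other scalings (quantile, median), normexp background correction with an offset of 50, the deposited table, other filters on dim probes, the mean of a gene's probes, eBayes with trend and robust settings, array weights, a replicate block and leaving out each array. A block for the row of the slide was chosen after seeing the data. Figures were drawn with matplotlib.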

Results

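Gene expression was measured in back skin of C57BL/6 mice aged 6 to 8 weeks. The backs of all 6 mice were shaved. From 2 days later, 3 mice were exposed to ultraviolet B light (UVB) at 180 mJ/cm2 in 3 sessions a week for 2 weeks, and the other 3, kept dark, served as controls. RNA of each mouse was hybridised to 1 Agilent mouse array in 1 colour, giving 6 arrays with 62976 spots each. Between 54.9% and 63.3% of the spots that were not controls lay well above background per array, and no spot was saturated. The number of arrays, 3 per group, limits the precision of every value. The time between the last exposure and sampling is not given in the sources used here. The comparison asks which transcripts differ between skin with and without UVB.

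After UVB, the skin carried far higher levels of hair shaft and inner root sheath genes, and higher levels of cornification and pigment genes. The largest fitted rises were those of Krt25 and Krt71, keratins of the inner root sheath, Padi3, an enzyme that modifies hair follicle proteins, Krtap22-2, a keratin-associated protein of hair, Tchhl1, a relative of trichohyalin, and Krt33b, a keratin of the hair cortex. Krt71 rose by a log2 fold change of 9.64 ± 0.83 (SE, n = 3 per group, limma adjusted p = 0.00353). Krt25 and Padi3 rose by 11.04 ± 1.43 and 10.26 ± 0.76 on the log2 scale, and each was well above background on 1 of the 3 control arrays. Krtap22-2, Tchhl1 and Krt33b were not well above background on any control array, and stood at least 495-fold, 646-fold and 524-fold higher after UVB (limma adjusted p = 0.00356, 0.00146 and 0.00253). The order of these genes is not established: with normexp background correction, Krt71 stood at 8.84, Krt25 at 7.86, Tchhl1 at 6.78, Padi3 and Krt33b at 6.51 and Krtap22-2 at 6.25 on the log2 scale, short of the bounds given for 3 of them. The largest fitted falls were those of Ifitm6, a member of the interferon-induced transmembrane family (log2 fold change -6.49 ± 0.58), Cdh4, a cadherin (-4.20 ± 0.24), Crispld2, a secreted protein (-3.75 ± 0.20), and Cxcl1, a chemokine that attracts neutrophils (-3.61 ± 0.43). Cdh4 and Cxcl1 were well above background on 1 of the 3 UVB arrays. Adgrv1 and Adgre4, both adhesion receptors, were not well above background on any UVB array and stood at least 11.6-fold and at least 4.24-fold lower after UVB. With normexp the log2 fold changes of these dim genes were smaller, -2.33 for Cdh4, -1.88 for Adgrv1, -1.54 for Cxcl1 and -1.02 for Adgre4, and the bounds were not reached. The same held for the lists below: with normexp, none of the 14 called list genes given as a bound reached it, and 36 of 162 called list genes were over 1.5 times smaller on the log2 scale, all with the same sign. The probes of Krt25 and Ifitm6 lie on chromosome 11 at 99177867 to 99178575 and on chromosome 7 at 148201714 to 148201773 of the mouse build mm9.

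Of 24355 targets tested, 14865 of them named genes, 1351 were higher and 1707 lower after UVB (limma, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was seen in 831 of the higher and 598 of the lower targets. The 2 groups did not overlap for 9375 targets, or 38.5%, where chance gives 10%. The first principal component held 63.0% of the variance and placed the 3 control arrays between -59.8 and -57.7 and the 3 UVB arrays between 41.4 and 83.6. Pearson correlations ran from 0.980 to 0.991 within groups and from 0.953 to 0.972 between them. Fewer were called with 5 arrays: without control replicates 1, 2 and 3 in turn 863, 468 and 957 were higher and 761, 391 and 805 lower, and without UVB replicates 1, 2 and 3 515, 859 and 843 were higher and 510, 879 and 1064 lower. At 2-fold or more, 450 were higher and 343 lower without control replicate 2, and 463 higher without UVB replicate 1. Of the 6318 genes with over 1 tested probe, 4199 had all probes in 1 direction, and this held for 669 of 757 called genes.

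**Figure D1:**
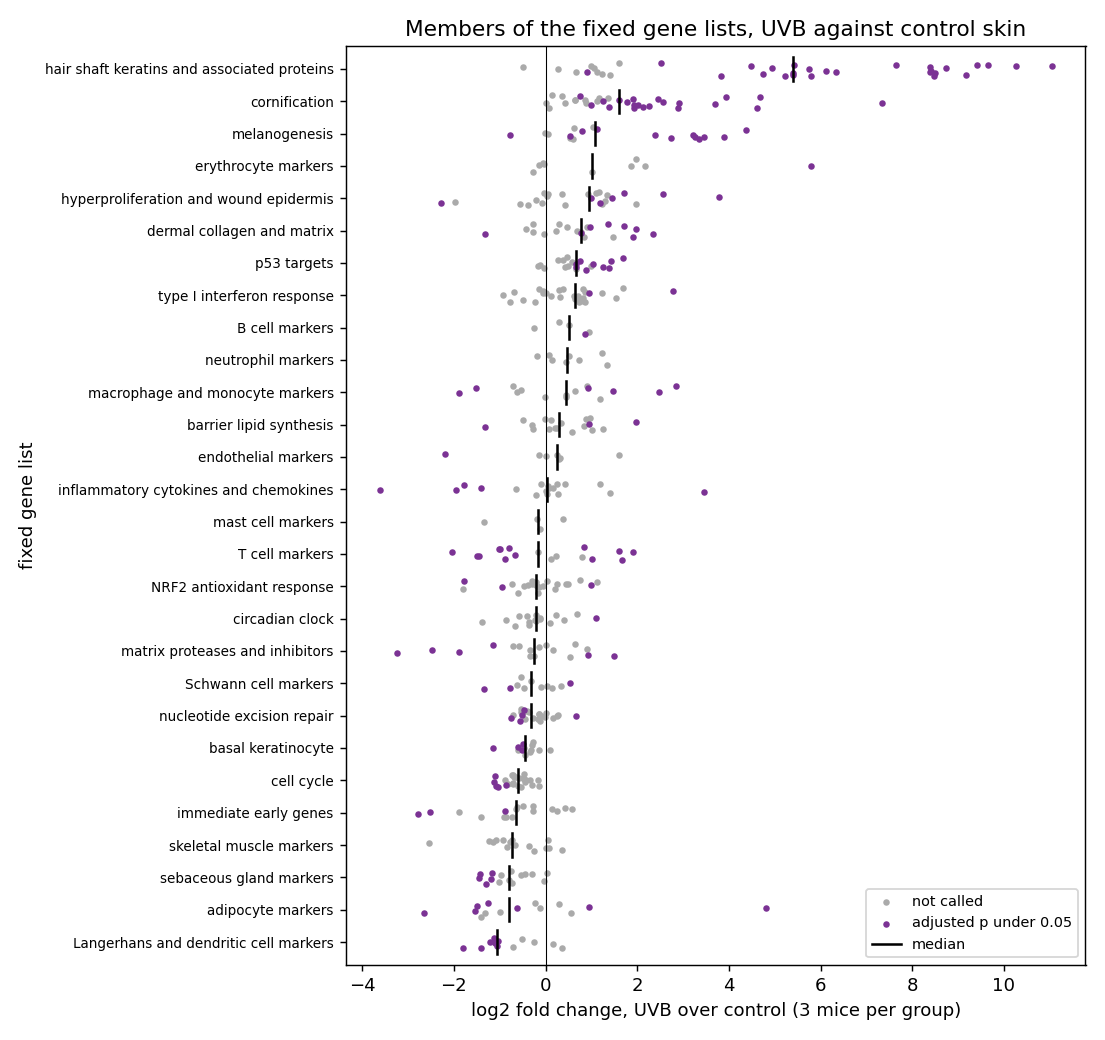
Each point is 1 measured member of a fixed gene list, placed by its log2 fold change of UVB over control skin (horizontal axis, 3 mice per group), with purple for an adjusted p under 0.05, grey for other members and a black line at the list median. The hair shaft list has the highest median, 5.39, and the Langerhans and dendritic cell list the lowest, -1.05.

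Hair shaft keratins and their partners rose as a group. Of 35 measured members, 26 rose and 9 did not pass the test, and 30 rose when adjusted over the list alone. The median log2 fold change was 5.39, also with the 7 members that have only a bound set to that bound. With normexp these 7 fell short of their bounds, so the median is not shown to hold under that correction. The inner root sheath keratin Krt27 rose by 8.48 ± 0.54 and the keratin-associated gene Krtap11-1 by 8.40 ± 0.62 on the log2 scale (limma adjusted p = 0.00224 and 0.00252). Of the transcription factors on the list, Dlx3 rose by 0.90 ± 0.17, while Hoxc13 (1.41 ± 0.38), Msx2 (1.06 ± 0.35), Lef1 (0.67 ± 0.58) and Foxn1 (0.27 ± 0.14) did not pass. The list stood above other genes (limma camera, adjusted p = 1.04e-21), with adjusted p = 0.331 with an estimated correlation. The probes of Krt85, a hair keratin, disagreed: the brightest gave -0.49 ± 0.21 and did not pass, while the other 2 gave 1.65 ± 0.27 and 8.06 ± 0.59.

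**Figure D2:**
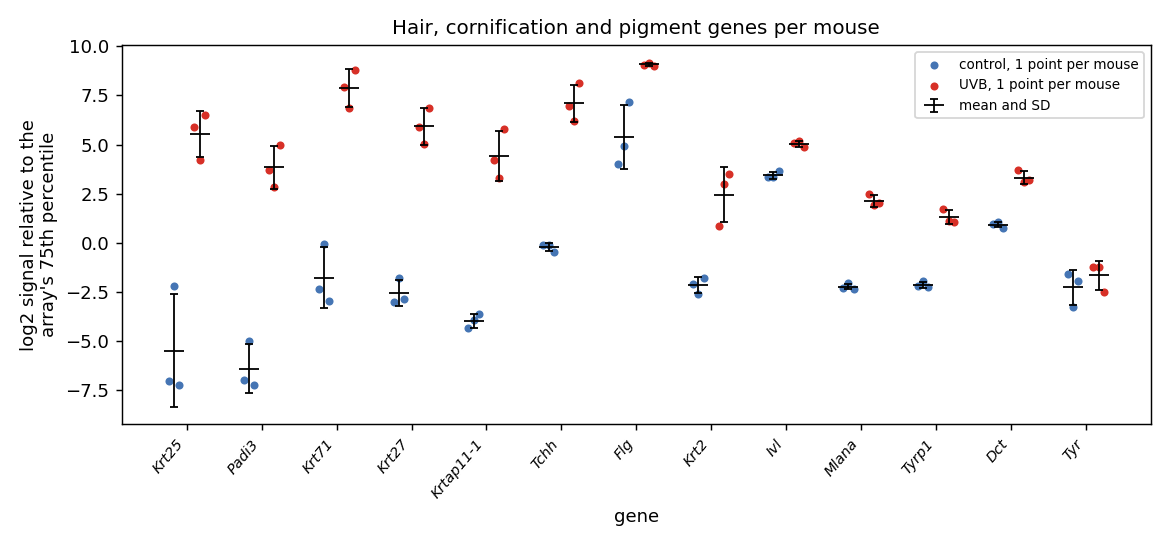
Each point is 1 mouse, with the log2 signal relative to the 75th percentile of its array on the vertical axis, control mice in blue, UVB mice in red, and bars at the mean and SD of 3 mice. All 3 UVB mice lie above all 3 control mice for every gene shown except Tyr, whose means are -2.27 in control and -1.66 in UVB skin.

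Genes of the cornified layer rose with them. Of 33 measured cornification genes, 21 rose and 12 did not pass, and 29 rose when adjusted over the list alone. The median log2 fold change was 1.61. Tchh, which encodes trichohyalin of the inner root sheath and some epidermis, rose by 7.33 ± 0.46. Ivl, which encodes the envelope precursor involucrin, rose by 1.61 ± 0.15 (limma adjusted p = 0.00224 and 0.00391). Filaggrin (Flg, 3.70 ± 0.75), Rptn (4.68 ± 0.65) and the late keratin Krt2 (4.62 ± 0.68) rose, as did 10 Lce1 and Lce3 genes of the late cornified envelope, by 1.91 to 3.94 on the log2 scale. Without control replicate 2 or UVB replicate 1, 11 and 13 members rose. Krt1 (1.13 ± 0.36) and Krt10 (0.42 ± 0.13), keratins of the spinous layers, did not pass. The list stood above other genes (limma camera, adjusted p = 2.56e-16), with adjusted p = 0.331 with an estimated correlation.

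Of 13 basal keratinocyte genes, 4 fell and 9 did not pass, and 5 fell when adjusted over the list alone. The log2 fold change was -1.15 ± 0.19 for integrin alpha 3 (Itga3) and -0.61 ± 0.12 for integrin alpha 6 (Itga6), which anchors basal cells (limma adjusted p = 0.0164 and 0.0251). Col17a1 and Trp63 also fell, although 1 of 4 Trp63 probes gave 0.59 ± 0.15. Adjusted over all probes, that rising probe passed (limma adjusted p = 0.0499), while the falling probe that stands for the gene did not (0.0521). Itga3 did not pass without control replicate 2 (limma adjusted p = 0.0670) or UVB replicate 1 (0.0598), nor Itga6 without any 1 array except UVB replicate 2 (0.0589 to 0.102), and at most 2 members passed with 1 array left out. The list stood below other genes (limma camera, adjusted p = 0.00109), with adjusted p = 0.331 with an estimated correlation. The list of hyperproliferation and wound epidermis genes was mixed: 6 of 24 rose, 1 fell, and 10 rose and 2 fell when adjusted over the list alone. Without UVB replicate 1 or 2, 3 of them rose, and without control replicate 3, 2 fell. Serpinb3a, a serine protease inhibitor, rose by 3.78 ± 0.37 and Stfa2, a stefin, by 2.57 ± 0.48, while Lcn2, which binds siderophores, fell by 2.28 ± 0.28. Krt6a (-0.20 ± 0.39) and Krt16 (0.36 ± 0.35), keratins of activated epidermis, did not pass (limma adjusted p = 0.764 and 0.525), and Krt6a changed sign without control replicate 1 (0.0215) and without control replicate 2 (0.0388). The list stood above other genes (limma camera, adjusted p = 0.00369), with adjusted p = 0.331 with an estimated correlation. Of 18 genes of barrier lipid synthesis, 2 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. Degs2, a ceramide desaturase, rose by 1.97 ± 0.31 but did not pass without control replicate 2 (limma adjusted p = 0.0627) or UVB replicate 1 (0.0610). Ugcg, which makes glucosylceramide, rose by 0.94 ± 0.21 and passed only with all arrays or without control replicate 3 (limma adjusted p = 0.0627 to 0.117 without the others), while Fa2h, a fatty acid hydroxylase, fell by 1.31 ± 0.32. Without control replicate 3, 6 of these genes rose, at most 1 rose without any other array, and the fall passed again only without control replicate 1. That list stood above other genes (limma camera, adjusted p = 0.0235), with adjusted p = 0.692 with an estimated correlation, and did not pass without control replicate 1 (adjusted p = 0.283) or UVB replicate 2 (0.0768).

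Melanocyte genes rose. Of 18 measured melanogenesis genes, 11 rose, 1 fell and 6 did not pass, and 12 rose and 1 fell when adjusted over the list alone. The fall, of Rab27a, passed again only without control replicate 1 or UVB replicate 2. Mlana, a melanosome protein, rose by 4.38 ± 0.19 and Tyrp1, an enzyme of melanin synthesis, by 3.45 ± 0.21 on the log2 scale (limma adjusted p = 0.001 and 0.00211). Dct, another such enzyme, rose by 2.40 ± 0.20, and Kitl, the ligand of the Kit receptor, by 1.13 ± 0.13. Slc45a2 and Oca2, melanosome transporters, were not well above background on any control array and stood at least 3.80-fold and at least 3.78-fold higher, but with normexp only 0.77 and 0.72 on the log2 scale. Tyr, the rate-limiting enzyme of melanin synthesis, had a log2 fold change of 0.61 ± 0.54 and did not pass (limma adjusted p = 0.484), and Mitf (0.06 ± 0.30) and Kit (-0.02 ± 0.30) lay near 0. The list median was 1.08, and the list stood above other genes (limma camera, adjusted p = 3.42e-09), with adjusted p = 0.331 with an estimated correlation.

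Of 20 measured p53 targets, 9 rose and 11 did not pass, and 16 rose when adjusted over the list alone. Ccng1, a cyclin, rose by 1.39 ± 0.17 and Aen, a nuclease of apoptosis, by 1.04 ± 0.14 (limma adjusted p = 0.00708 and 0.00942), and Trp53inp1, Ddit4l and Plk3 also rose. Fewer passed without 1 array, with 2 without control replicate 2, 4 without UVB replicate 1, 4 without UVB replicate 2 and 5 without control replicate 1. The probes of Cdkn1a, which encodes the cell cycle inhibitor p21, differed in size. The brightest, on chromosome 17 at 29237377 to 29237436 of mm9, gave 0.48 ± 0.17 and did not pass (limma adjusted p = 0.116), while the probes starting at 29235299 and 29227986 gave 1.44 ± 0.31 and 4.08 ± 0.22 and passed among all probes (limma adjusted p = 0.0350 and 0.00127). The p53 list stood above other genes (limma camera, adjusted p = 7.28e-08), with adjusted p = 0.331 with an estimated correlation. All 27 cell cycle genes had negative log2 fold changes, of which 5 passed, and 14 fell when adjusted over the list alone. Among these 14 was Cdk1, whose 2 probes disagreed: the brighter gave -0.81 ± 0.21 and the other 0.87 ± 0.24, and neither passed over all probes. Mcm2 and Mcm6, subunits of the replicative helicase, changed by -1.11 ± 0.13 and -1.03 ± 0.14 on the log2 scale (limma adjusted p = 0.00694 and 0.00921), as did Mcm3, Mcm5 and Bub1b, while the proliferation marker Mki67 (-0.14 ± 0.17) did not pass and had the other sign without control replicate 2 (0.0187). Without control replicate 2 or 3, 3 members fell, and without UVB replicate 1, 2 fell. The cell cycle list stood below other genes (limma camera, adjusted p = 3.21e-07), with adjusted p = 0.588 with an estimated correlation.

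Of 24 genes of nucleotide excision repair, 4 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone. Pcna, the sliding clamp, fell by 0.76 ± 0.12, and Gtf2h4, Ercc8 and Rpa1 fell too, while Ercc5, an endonuclease and also a member of the p53 list, rose by 0.67 ± 0.12 (limma adjusted p = 0.0166 for Pcna and 0.0198 for Ercc5). Pcna did not pass without control replicate 2 (limma adjusted p = 0.0782) or UVB replicate 1 (0.0641), nor Ercc5 without control replicates 1 or 2 or UVB replicates 1 or 2 (0.0539 to 0.0832), and 0 to 1 members fell with 1 array left out. The list stood below other genes (limma camera, adjusted p = 0.0189), with adjusted p = 0.692 with an estimated correlation and 0.0590 without UVB replicate 3. Immediate early genes, which respond to stimuli within minutes, fell in 3 of 17 cases, and 5 fell when adjusted over the list alone: the nuclear receptors Nr4a1 (-2.77 ± 0.64) and Nr4a2 (-2.51 ± 0.53) and the transcription factor Egr1 (-0.88 ± 0.21) passed over all genes, Nr4a2 with -1.44 under normexp. Nr4a1 passed in 5 arrays only without control replicate 2 (limma adjusted p = 0.0569 to 0.117 otherwise) and Nr4a2 only without control replicate 3 (0.0512 to 0.0894 otherwise). A count of 3 falling members was reached again only without control replicate 2, where Nr4a2 was not among them (limma adjusted p = 0.0512). At most 1 member fell without any other array. That list stood below other genes (limma camera, adjusted p = 0.0308), with adjusted p = 0.692 with an estimated correlation, and did not pass without control replicate 3 (adjusted p = 0.132), UVB replicate 2 (0.0570) or UVB replicate 3 (0.0782). Of 23 NRF2 antioxidant genes, Gsta1 rose by 0.99 ± 0.19 and Fth1 and Gsta3 changed by -0.95 ± 0.12 and -1.78 ± 0.31, with 2 higher and 3 lower when adjusted over the list alone (limma camera, adjusted p = 0.407). The rise passed again only without control replicate 1 or 3, and 1 of the falls was left without control replicate 1 or 2 or UVB replicate 1 or 2. Of 17 circadian clock genes, 1 rose, Nfil3 (limma adjusted p = 0.0186), also when adjusted over the list alone (limma camera, adjusted p = 0.571). None of the clock genes passed without control replicate 1, control replicate 2 or UVB replicate 1, and 2 rose without control replicate 3.

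Markers of Langerhans and dendritic cells fell, and T cell markers moved apart. Of 12 measured Langerhans and dendritic cell markers, 7 fell and 5 did not pass, and 8 fell when adjusted over the list alone. The log2 fold change was -1.41 ± 0.18 for Cd207, the Langerhans cell lectin langerin, and -1.05 ± 0.15 for Cd74, the invariant chain of MHC class II (limma adjusted p = 0.00832 and 0.0108), and the class II genes H2-Aa, H2-Ab1 and H2-Eb1 fell too. Without control replicate 2 Cd74 did not pass (limma adjusted p = 0.0537) and 2 members fell, against 3 without UVB replicate 1 and 4 without control replicate 1 or 3. The list stood below other genes (limma camera, adjusted p = 0.000907), with adjusted p = 0.527 with an estimated correlation. Of 17 T cell markers, 8 fell and 5 rose, and 8 fell and 6 rose when adjusted over the list alone. The T cell receptor components Cd3g (-2.05 ± 0.18) and Cd3d (-1.45 ± 0.16) fell, as did the kinase Zap70. Icos, a costimulatory receptor, and Gzma, a granzyme of cytotoxic cells, rose by 1.92 ± 0.16 and 1.67 ± 0.22, and Cd8a, not well above background on any control array, stood at least 2.56-fold higher. With normexp these 3 rises were 0.95, 0.65 and 0.32 on the log2 scale. As a list they stood neither above nor below other genes (limma camera, adjusted p = 0.659). With 1 array left out, 3 to 5 of them fell, the fewest without control replicate 2 or UVB replicate 1, and 3 to 4 rose, 3 without control replicate 2 or 3 or UVB replicate 1 or 2.

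Macrophage and monocyte markers also split: of 15, 4 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. Adgre1, a macrophage surface receptor (-1.88 ± 0.11), and Csf1r, a growth factor receptor (-1.52 ± 0.17), fell, while Ms4a7, well above background on 2 of 3 control arrays, rose by 2.85 ± 0.60, and Ccr2, not well above background on any control array, stood at least 3.50-fold higher (limma camera for the list, adjusted p = 0.244). With normexp Ms4a7 and Ccr2 stood at 1.47 and 0.52 on the log2 scale, and the probes of Itgam, 1 of the 6 that rose over the list alone, had both signs (-0.18 to 0.64). With 1 array left out, 0 to 3 of these markers rose, none without control replicate 2, UVB replicate 1 or UVB replicate 2 and 2 without UVB replicate 3. Among 18 cytokines and chemokines, Tnf (-1.79 ± 0.15, and -1.03 with normexp), Ptgs2, the inducible cyclooxygenase (-1.95 ± 0.28), Il33 and Cxcl1 were the 4 that fell, and Ptgs2 did not pass without UVB replicate 1 (limma adjusted p = 0.0503). Ccl8, a chemokine, rose by 3.46 ± 0.72, and the counts were 1 higher and 4 lower when adjusted over the list alone. The rise passed again only without control replicate 1 or UVB replicate 3, and 2 falls were left without UVB replicate 1. Il1b had a log2 fold change of 0.01 ± 0.20, below 0 under 4 other scalings (-0.0885 to -0.0373). The median of that list was 0.04 and its mean -0.13, and camera placed it below other genes without passing (adjusted p = 0.734). Of 28 type I interferon response genes, Cxcl9, a chemokine, rose by 2.78 ± 0.38 and Mx1, an antiviral GTPase, by 0.95 ± 0.21 (limma adjusted p = 0.00986 and 0.0343, and 0.0700 to 0.110 for Mx1 without any 1 array except control replicate 1), and 4 rose and 2 fell when adjusted over the list alone. Without control replicate 2 or 3 or UVB replicate 1 or 2, 1 member rose. The list stood above other genes (limma camera, adjusted p = 0.0206), with adjusted p = 0.692 with an estimated correlation, and did not pass without control replicate 3 (adjusted p = 0.553), UVB replicate 1 (0.0698) or UVB replicate 2 (0.0847). Of 18 neutrophil markers 8 were tested, and none passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 4 were higher, led by S100a8 (1.35 ± 0.40) and Trem1 (0.51 ± 0.16). S100a8 is also on the list of hyperproliferation and wound epidermis genes, so its rise need not come from neutrophils. The neutrophil list stood above other genes (limma camera, adjusted p = 0.0235), with adjusted p = 0.331 with an estimated correlation and 0.0567 without UVB replicate 3. Of 5 B cell markers, 1 rose, and 2 rose when adjusted over the list alone (limma camera, adjusted p = 0.106). That rise did not pass without any 1 of the 6 arrays. None of the 4 measured mast cell markers passed in limma or at an unadjusted p under 0.05, and the list was too short for a test.

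**Figure D3:**
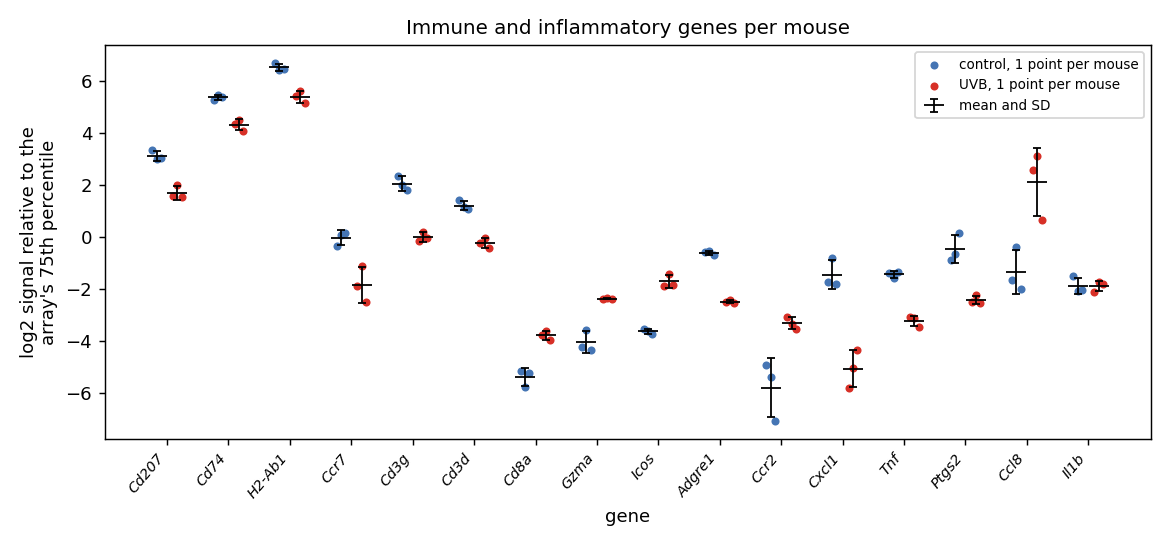
Each point is 1 mouse, with the log2 signal relative to the 75th percentile of its array on the vertical axis, control mice in blue, UVB mice in red, and bars at the mean and SD of 3 mice. Cd207, Cd74, Cd3g and Adgre1 are lower and Cd8a, Gzma and Icos higher in all 3 UVB mice, while the groups overlap for Il1b.

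Of 20 measured genes of the fixed list of dermal collagen and matrix, 7 rose, 1 fell and 12 did not pass, and 9 rose and 1 fell when adjusted over the list alone. Col1a1 and Col3a1, chains of the fibrillar collagens, rose by 2.35 ± 0.46 and 1.91 ± 0.43 on the log2 scale, and the microfibril protein Mfap4 rose by 1.98 ± 0.32, while Postn, which encodes periostin, fell by 1.31 ± 0.16. Col1a1 did not pass without control replicate 1 or any 1 UVB array (limma adjusted p = 0.0546 to 0.0855), nor Mfap4 without control replicate 2, UVB replicate 1 or UVB replicate 2 (0.0515 to 0.0587), and between 0 and 4 members of the list rose with 1 array left out. The list stood above other genes (limma camera, adjusted p = 0.00124), with adjusted p = 0.570 with an estimated correlation. Among 17 matrix proteases and inhibitors, 4 fell and 2 rose, and 4 fell and 3 rose when adjusted over the list alone. Mmp9 (-2.47 ± 0.34, and -0.91 with normexp) and Mmp3 (-1.88 ± 0.42) were among those that fell, while Mmp11 rose by 1.49 ± 0.33 (0.71 with normexp) and Mmp13 (0.54 ± 0.66) did not pass, with the other sign without control replicate 3 (-0.23). Mmp3 did not pass without any 1 of the 6 arrays except control replicate 3 (limma adjusted p = 0.0613 to 0.119). Of the 2 rises, 1 was left without control replicate 2 or 3 or UVB replicate 1 or 2, and the list did not pass (limma camera, adjusted p = 0.479).

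Sebaceous gland markers fell in 5 of 15 cases, also when adjusted over the list alone. Plin2, a lipid droplet protein (-1.44 ± 0.18), and Mgst1, a glutathione transferase (-1.17 ± 0.17), fell (limma adjusted p = 0.00752 and 0.0127, and 0.0515 for Mgst1 without control replicate 2, where 1 member of the list fell, against 3 without control replicate 3, UVB replicate 2 or UVB replicate 3), and Scd1, Soat1 and Cidea fell as well. The list stood below other genes (limma camera, adjusted p = 0.000878), with adjusted p = 0.570 with an estimated correlation. Adipocyte markers were mixed: of 14, 5 fell and 2 rose, and 7 fell and 2 rose when adjusted over the list alone. Pparg, the adipocyte transcription factor (-1.53 ± 0.16), and Lpl, lipoprotein lipase (-1.26 ± 0.21), fell, while Fabp4, a fatty acid carrier, rose by 4.80 ± 0.77 (limma camera, adjusted p = 0.0663, and 0.00748 without control replicate 1). Without control replicate 2 or UVB replicate 2, 1 adipocyte marker fell, and without UVB replicate 1, 3 fell and none rose. At most 1 rose without any other array except control replicate 3. None of 15 skeletal muscle markers passed in limma, over all genes or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05 (limma camera, adjusted p = 0.118, and 0.00197 without control replicate 3). Of 7 endothelial markers, Lyve1, a lymphatic receptor not well above background on any UVB array, stood at least 2.22-fold lower, also when adjusted over the list alone (limma camera, adjusted p = 0.603). It passed again only without control replicate 3 or UVB replicate 3, and its log2 fold change was -0.51 with normexp. Of 11 Schwann cell markers, the myelin genes Pmp22 (-1.34 ± 0.20) and Mbp (-0.78 ± 0.15) fell and Sox10, which melanocytes share, rose by 0.53 ± 0.12, with the same counts when adjusted over the list alone (limma camera, adjusted p = 0.354). The rise did not pass with normexp (0.27 on the log2 scale) or without any 1 array, neither fall passed without control replicate 2, and both passed again only without UVB replicate 2. Of 9 erythrocyte markers, Ahsp, the alpha globin chaperone, stood at least 13.5-fold higher and alone passed, also when adjusted over the list alone, while Hbb-bs (2.18 ± 0.71, well above background on 2 of 3 control arrays) did not. With normexp the log2 fold change of Ahsp was 1.88, short of that bound, and of Hbb-bs 0.79. The erythrocyte list stood above other genes (limma camera, adjusted p = 0.0429), with adjusted p = 0.692 with an estimated correlation, and did not pass without control replicate 1 (adjusted p = 0.0563), control replicate 3 (0.0834) or UVB replicate 3 (0.351).

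The labels call all 6 mice male. Xist, the RNA of the inactive X chromosome, was well above background on all 6 arrays with both of its probes. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background on 0 of the 6 arrays with any probe. These values argue against the male label for all 6 mice. The 2 groups did not differ in this pattern.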

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

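The row of the slide was chosen as a block after seeing the data, and the other alternatives were planned. No call of a named gene reversed: 43 of the 45 named genes called kept their call under the 4 other scalings, 30 without each array in turn and 16 under every alternative run. Without each array in turn the counts ran from 468 to 957 higher and 391 to 1064 lower, and at 2-fold or more from 450 to 782 higher and 343 to 613 lower. Fewer arrays were fitted there, and the lowest counts came without control replicate 2. The replicate numbers did not pair the mice: the correlations of deviations from the group means were -0.11, -0.26 and -0.08 for numbers 1, 2 and 3, and no mouse correlated best with its own number. With the replicate block 472 higher and 301 lower genes were called (465 and 294 at 2-fold or more), and the skeletal muscle list passed (adjusted p = 0.00172). All arrays lay on 1 slide, so the slide block was not run. Its first row held the 3 control arrays and UVB replicate 1, and the second only UVB arrays, so a row block compares UVB replicate 1 with the controls: it called 106 higher and 122 lower genes, all of at least 2-fold. With it, the lists of barrier lipid synthesis (adjusted p = 0.0541), erythrocytes (0.523), immediate early genes (0.135), neutrophils (0.0643) and nucleotide excision repair (0.0802) no longer passed, and the circadian list passed (0.0482). Array weights raised the calls to 2413 higher and 3123 lower, with no filter 1061 were lower, and normexp left 271 lower at 2-fold or more. Median scaling moved the median log2 fold change of all genes from -0.04 to -0.14, and the share of higher calls from 44.2% to 35.4%. Under these settings most list calls stood, and the cause of each change below was not tested. The erythrocyte list did not pass with quantile normalization (0.0523), normexp (0.0662), no filter (0.103), probes above background on all 6 arrays (0.223) or array weights (0.127). The immediate early list did not pass with quantile normalization (0.0529), normexp (0.0557), the deposited values (0.0599) or array weights (0.265). With no filter, barrier lipid synthesis (0.192), hyperproliferation (0.0514), neutrophils (0.204) and the interferon list (0.200) did not pass, while adipocytes (0.00566) and skeletal muscle (0.0175) did, and adipocytes also passed with trend and robust settings (0.0492) and array weights (0.0432).

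With an estimated correlation no list passed: adjusted p was 0.331 for the hair shaft, cornification, melanogenesis, p53, basal keratinocyte, hyperproliferation and neutrophil lists, 0.527 for Langerhans and dendritic cells, 0.570 for dermal matrix and sebaceous gland, 0.588 for cell cycle and 0.692 for barrier lipids, erythrocytes, immediate early genes, nucleotide excision repair and interferon. The directional fry test passed for melanogenesis (adjusted p = 0.00599), p53 (0.00896), basal keratinocytes (0.00896), hair shaft (0.0117) and cornification (0.0196). It also passed for Langerhans and dendritic cells (0.0254), hyperproliferation (0.0392) and neutrophils (0.0394). It gave 0.0535 for cell cycle, nucleotide excision repair and sebaceous gland, 0.0843 for dermal matrix, 0.215 for erythrocytes and 0.235 for immediate early genes. Barrier lipids (0.327) and interferon (0.492) did not pass it either, and it placed macrophage markers lower (0.757). The mixed fry test, which asks for change either way, did not pass for interferon (0.130) and passed for lists that camera did not call: B cells (0.0274), NRF2 (0.000336), Schwann cells (0.000486), T cells (1.97e-05), adipocytes (0.000336), circadian clock (0.00334), endothelium (0.0254), cytokines (9.41e-06), macrophages (1.92e-05) and matrix proteases (3.57e-05). Without each array in turn, adjusted p ran from 0.00748 to 0.189 for adipocytes, 0.000112 to 0.283 for barrier lipids, 0.133 to 0.967 for the circadian clock, 0.177 to 0.811 for endothelium, 0.00889 to 0.351 for erythrocytes, 0.000425 to 0.132 for immediate early genes, 0.489 to 0.897 for cytokines, 0.0202 to 0.0567 for neutrophils, 0.00962 to 0.0590 for nucleotide excision repair, 0.00197 to 0.325 for muscle and 0.000850 to 0.553 for interferon. The direction turned for the circadian list without control replicate 3 (0.856), endothelium without UVB replicate 3 (0.695) and cytokines without control replicate 1 (0.897), none of them past the threshold. Among named genes that were not called, Il1b turned sign with quantile normalization (-0.0490), median scaling (-0.0885), normexp (-0.0373), the deposited values (-0.0701), the row block (-0.208) and some left-out arrays (-0.0892 to 0.198), and Krt16 with array weights (-0.0487). Left-out arrays gave -0.652 to 0.0388 for Krt6a, -0.224 to 0.0187 for Mki67 and -0.232 to 0.979 for Mmp13. Dim probes are limited by background: between 54.9% and 63.3% of spots lay well above it.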

Other observations

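The tests in this part were chosen after the results they bear on were seen, except those on other scalings of the hair genes, on level and GC content of probes, and on the distance bands of probe pairs. Among 526 families of named genes that share the letters opening their symbol, with at least 5 tested members, 12 held more calls in 1 direction than chance gives (hypergeometric test, Benjamini-Hochberg adjusted over 1052 tests), with genes counted as if independent. Keratin-associated protein genes (Krtap) rose in 36 of 49 cases (adjusted p = 1.63e-31) and late cornified envelope genes (Lce) in 15 of 16 (adjusted p = 1.83e-15). Serine proteases of the Tmprss family rose in 5 of 10 cases (adjusted p = 0.0184), among them Tmprss11a (log2 fold change 3.95 ± 0.54, well above background on 2 of 3 control arrays) and Tmprss11e (2.91 ± 0.41), and kallikreins (Klk) in 6 of 19 (adjusted p = 0.0448), led by Klk13 (2.83 ± 0.22). Of 7 glucuronosyltransferase genes (Ugt), 5 rose (adjusted p = 0.00316), with Ugt1a6a, well above background on 2 of 3 control arrays, at 2.89 ± 0.22. Carboxylesterases (Ces) split: Ces2c, Ces2e, Ces2f and Ces2g rose, with Ces2e at 3.31 ± 0.32, while Ces1d (-1.84 ± 0.22) and Ces1e (-1.69 ± 0.17, well above background on 2 of 3 UVB arrays) fell (adjusted p = 0.0387 for the rise). Serpinb genes rose in 6 of 18 cases and fell in 3 (adjusted p = 0.0387 for the rise).

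Of 17 regulators of G protein signalling (Rgs), 8 fell and 1 rose (adjusted p = 0.0173), with Rgs1 at -2.09 ± 0.29. Of 5 Klrb genes, receptors of natural killer cells and some T cells, 4 fell (adjusted p = 0.0425), and Klrb1b fell by 2.08 ± 0.30. Of 10 Mcm genes, 6 fell (adjusted p = 0.0184), Mcm4 and Mcm7 besides the 4 of the cell cycle list. Of 78 genes whose symbol opens with Cd, a mixed set, 20 fell and 7 rose (adjusted p = 0.0112 for the fall). Cd7 (-2.52 ± 0.19) and Cd96 (-1.79 ± 0.15) fell, while Cd24a (1.73 ± 0.15) and Cd93 (2.73 ± 0.57) rose. Keratins (Krt) rose in 20 of 46 cases and fell in 1, Krt77 (adjusted p = 6.25e-11 for the rise). Under the 4 other scalings the direction with more calls was the same for each family except Serpinb, which had 6 genes higher and 6 lower with normexp.

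Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many genes as the real split, itself, with 3058 calls against a highest of 0 in the others (limma, up to 1134 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Each other split mixes control and UVB arrays, so that a large group difference enters its residual spread and few calls are given in advance.

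Hair shaft genes stood higher in all 3 UVB arrays, with list means of 1.59 to 3.76 against -2.84 to -2.42 in controls on the log2 scale. Cross-hybridisation between keratins is argued against as the whole source by the 4 of 8 members outside the keratin families that rose, and the scaling by at least 26 members rising under each of the 4 other scalings. A growing phase of the hair cycle in the UVB mice is a candidate explanation, and whether UVB or chance assortment of the equally shaved mice by hair cycle stage set it stays open, since the hair cycle stage of the mice is not given in the sources used here. The exact two-sided permutation p of the list means, 0.1, is the lowest that 3 mice against 3 allow and decides nothing. Pigment cell genes of growing follicles may rise with the same stage. Not all values go with a growing phase. All 27 cell cycle genes had negative log2 fold changes, with a median of -0.60. Of the transcription factors on the hair list, Dlx3 passed, while Hoxc13, Msx2, Lef1 and Foxn1 were positive but did not pass. Tyr was positive and did not pass either. With 3 mice per group, positive values that did not pass decide nothing for or against a growing phase.

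Genes with distant probes showed a shift along the gene, tested after the probes of Wwox were seen to disagree: along the gene they stood at -1.18, 0.49 and -2.63 on the log2 scale, the last 2 under 1 kb apart, so that Wwox itself does not show a graded shift. Where the outermost tested probes lay at least 100 kb apart (117 genes), the median of downstream minus upstream log2 fold change was -0.309, negative in 84 of them, against 0.01 in 3116 genes under 10 kb (permutation p = 1e-05, the smallest the resampling can give), and the 3 UVB arrays (-0.21 to 0.02) lay below the 3 controls (0.08 to 0.22), but with normexp that median was -0.187. The difference was -0.41 among pairs alike in level (33 wide pairs) and -0.32 among pairs alike in GC content (74 wide pairs, both permutation p = 1e-05), which argues against signal level and GC content as the whole cause. RNA integrity stays open: the shift was -0.0734 at 10 to 50 kb but -0.214 at 50 to 100 kb, and distances along the transcript, on which degradation depends, were not measured, so the bound set beforehand on the nearer band alone was judged too weak once the values were seen. Transcription stopping before the end of long genes, as DNA lesions can do, is another candidate explanation, with alternative transcripts untested, genes not independent replicates, and few long genes covered, which was accepted after the value was seen, and the test itself was rerun after a strand coding error had given a wrong first value.

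Between genes, no fall with probe span was seen: genes with probes at least 100 kb apart differed by 0.0416 in median log2 fold change from those under 10 kb (permutation p = 0.255), by -0.0146 matched on level and by 0.0414 matched on GC content. That check, which was run before the one within genes, is void for length in general, since only 34.3% of named genes tested had 2 or more mapped probes.

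Langerhans and dendritic cell markers fell further than basal keratinocyte genes, with medians differing by -0.60 (permutation p = 0.0208). That permutation shuffled genes between the lists, as if independent, and holds no spread between mice. The estimated correlation within the Langerhans and dendritic cell list was 0.36. The p therefore does not decide whether a lower share of epidermis is the whole cause. A lower share of all immune cells is argued against as the whole cause by 9 T cell, macrophage and monocyte markers that rose, beside 10 that fell, although 3 rose without control replicate 2, UVB replicate 1 or UVB replicate 2. Lower class II expression alone would leave out the falls of Cd207 (-1.41 ± 0.18), Ccr7 (-1.80 ± 0.36) and Cd86 (-1.09 ± 0.24). Fewer Langerhans cells may give the fall and stay untested.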
